A study of Rattus norvegicus with 40 samples.

How the data were processed

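Gene expression was measured in whole intestine and lung of Wistar rat embryos at gestational days 16 (E16) and 20 (E20) on 40 Affymetrix rat expression arrays, 10 for each combination of tissue and age. Per the labels' protocols, total RNA was extracted with Trizol and labelled by a single-cycle biotin protocol from 1 µg of RNA for intestine and 2 µg for lung, so tissue and the amount of RNA labelled go together and cannot be told apart. The labels speak of tissue of several siblings being frozen, and the design text of 10 embryos at each age. Whether an array holds RNA of a single embryo or of several is not settled by the labels. In 38 of the 40 arrays 1 of the sex-linked transcripts Xist and Eif2s3y lay above the median level and the other was dim. The p-values measure only the spread between these samples, which may be partly technical. Litter was not part of the fit, so the spread between litters was not measured. If the arrays of an age come from siblings, age and litter cannot be told apart.

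The deposited values are normalized summary intensities on a linear scale, with a value for each of 31099 probe sets (a probe set is a group of short oligonucleotides for a transcript). RMA, a method that corrects background, normalizes between arrays and summarises probes, is the tool named in the submitters' processing notes, with no version. Whether both tissues were normalized together is not given in the sources used here, and no detection calls were used. The deposited intensities ran from 6.65 to 39901 over all arrays, and array medians from 220 to 264. The planned test assumed log2 values, whereas the deposited intensities were linear; log2 was therefore taken here before any test. Because arrays have no sequencing depth, their number limits the precision, and no detection limit was computed.

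Probe sets were named with the platform annotation supplied with the series. Of the probe sets, 20832 had 1 gene symbol, 436 had several and 9831 had none, and 57 were control probe sets. The Entrez identifiers of 20758 of those with 1 symbol were found in a table of rat genes for the GRCr8 assembly, which was used for names only; no coordinates are given, since the deposited table states no genome build. Each gene was represented by its probe set with the highest mean over the 40 arrays, which gave 14217 genes. Every column of sample values in the table was used.

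The test was limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 4 groups to all 40 arrays, without covariates, and 5 contrasts were taken: E20 minus E16 in intestine and in lung, the difference between these changes, and lung minus intestine at each age. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 14217 genes and a fold of at least 2 (a log2 difference of at least 1 in size), two-sided. Standard errors (SE) come from this fit, and SD is the spread of log2 intensity over the 10 arrays of a group. Calls shared between tissues were set against the number expected of independent lists, with Fisher's exact test across genes, which are not independent of each other.

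Before the data were examined, 47 gene lists were fixed, covering cell types and pathways of both organs, markers of other tissues that dissection could bring along (erythroid cells, liver, exocrine pancreas, stomach and oesophagus, cardiac and skeletal muscle, cartilage, mesothelium, thyroid and other neck endocrine tissue) and sex-linked genes. The 46 lists with at least 5 measured members were tested with limma's camera, which compares the members of a list with all other genes, at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over the lists of a contrast. The same test with the correlation estimated from the arrays was an alternative. A list call is said to hold where that adjusted p was also under 0.05. Adjusted over the list alone, the counts of called members equalled those over all genes in all 46 lists for 4 of the contrasts and in 44 lists for the difference between tissues. In the lists called by camera, median, mean and test had the same sign in all 5 contrasts. Among lists that were not called, they differed in sign in 5 lists for intestine, 3 for lung, 3 for the difference, 10 at E16 and 5 at E20.

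The genes named in the text were chosen by a rule fixed before the data were examined: for each age comparison the 5 largest rises and falls among called genes, of which the brighter group mean lay above the median of all log2 values (7.89), with no overlap between the arrays of the groups compared, a probe set naming 1 gene and without the suffix of cross-hybridising sets, and an established symbol; up to 4 called members of each list with the largest change; a short set of genes named in advance for intestine or lung, whatever their value; and, by the same criteria, the largest differences between tissues, the genes called in opposite directions, the largest lung and intestine contrasts called at both ages and the largest changes shared by both tissues. For the difference between tissues, the absence of overlap was required in at least 1 tissue, and sex-linked genes were not named. A member that moved against its list was also named, chosen after its value was seen, as were liver transcripts. Of the genes named in advance, Lct is not analysed here. A gene is called dim in a group whose mean is under the 30th percentile of all log2 values (6.86), where background is a large part of the signal and differences are compressed.

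The fit was tested on simulated data in which 200 of the 14217 genes were changed, 50 at each of 4 sizes. For the intestine age comparison, 0% of the genes changed 1.5-fold, 44% of those changed 2-fold and 100% of those changed 3-fold or 4-fold were called, with 0 of the unchanged genes called. For the lung age comparison, the shares were also 0%, 44%, 100% and 100%, with 1 unchanged gene called. For the difference between tissues, they were 0%, 56%, 98% and 100%, with 1 unchanged gene called. For the tissue comparisons at either age, they were 0%, 56%, 100% and 100%, with 0 unchanged genes called. The 2-fold minimum largely sets these shares and the few false calls. By the adjusted p alone, 86% of the genes changed 1.5-fold and 98% of those changed 2-fold passed in intestine, with 9 unchanged genes. In lung they were 94% and 100%, with 15 unchanged genes. In the simulated intestine comparison, camera called all 3 shifted lists and 0 of the others. The simulated genes were drawn independently of each other. In the arrays the estimated correlation was 0.648 in the mitosis list and 0.172 in the brush border list. False calls among lists of correlated genes were therefore not tested by the simulation.

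Alternatives fixed before the data were examined were quantile normalization, centring of each array on its median, bright genes only, the mean of a gene's probe sets, leaving out probe sets with cross-hybridisation suffixes, fits on only the groups compared, replicate number as a block, age and number as a random block, array weights, a variance trend with a robust prior, other fold thresholds, a test against a fold of 2, and leaving out each array in turn. A second liver list of 18 measured genes, outside the fixed lists, was written after liver transcripts were seen and before the values of its genes were. Chosen after seeing the data were the Xist level as a covariate, leaving out 9 arrays with transcripts of other tissues, and leaving out intestine E16 replicate 8. The 9 arrays stood over 0.75 log2 units above their group median in a list of another tissue. They are called the arrays that hold other tissues, a name that leaves the source of these transcripts open. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.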

Results

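Expression of 14217 genes was compared between whole intestine and lung of rat embryos at E16 and E20, with 10 arrays in each of the 4 groups. By its title the study asked which changes prepare these organs for birth, after which the intestine takes up milk and the lung breathes air. Array medians lay between 220 and 264 intensity units, with lower quartiles of 84.2 to 118 and upper quartiles of 625 to 652. At E16 the tissues did not overlap in array median (241 to 264 in intestine, 220 to 234 in lung). Their lower quartiles did not overlap there either (97.2 to 118 in intestine, 87.1 to 94.6 in lung). The first 3 principal components of the 9772 genes whose mean lay above the median of all log2 values held 47.8%, 33.0% and 9.58% of the variance, and the groups did not overlap on the first pair. Within groups, the median correlation of an array with the others ranged from 0.964 (intestine E16 replicate 8) to 0.989. No pair of arrays was alike enough to be a duplicate, the closest correlating at 0.994.

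**Figure D1:**
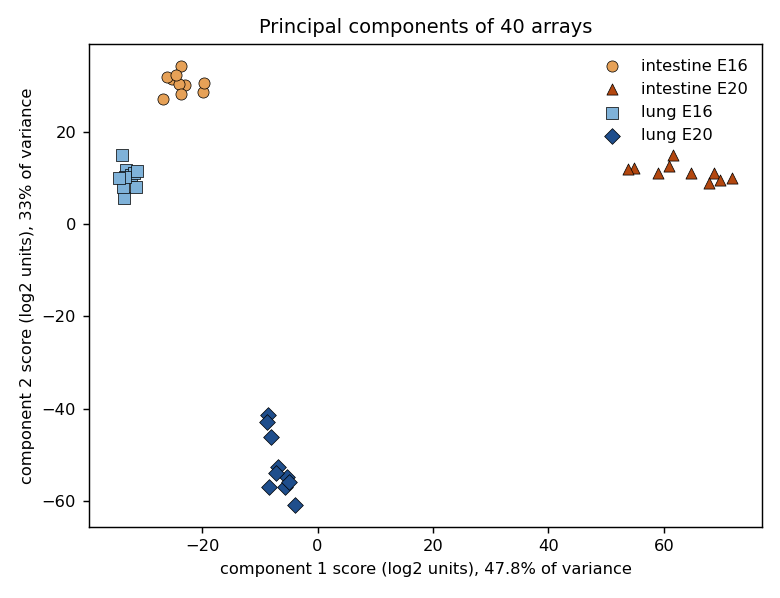
Scores of the 40 arrays on the first (x axis, 47.8% of variance) and second (y axis, 33.0%) principal component of log2 intensity, with a point per array and a colour and symbol per group. The groups of 10 arrays form separate clusters, those of both tissues lying closer together at E16 than at E20.

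In the intestine, transcripts for digesting and absorbing milk nutrients, for mucus and for epithelial junctions were far higher at E20 than at E16, while embryonic globins and most Hox genes were lower. The largest rise was that of Rbp2, the retinol-binding protein of absorptive cells, from 6.02 ± 0.28 to 14.03 ± 0.23 log2 units (SD, n = 10 arrays each; change 8.01, SE 0.12, limma adjusted p = 3.21e-39). It was followed by Clca1, a protein secreted by goblet cells (7.75), and the apolipoprotein Apoa1 (7.52). Next were Mttp, which loads lipid onto apolipoprotein B (7.51), and Prap1, a proline-rich acidic protein (7.40). The largest falls were in the embryonic globins Hbz (from 13.77 ± 0.31 to 6.36 ± 0.26, SD, n = 10; change -7.41, SE 0.13, limma adjusted p = 9.27e-37), Hbe1 (-6.29) and Hbg1 (-5.49). Large falls were also seen in Bnc1, a zinc-finger protein also in the mesothelium list (-4.25), and Slc4a1, the anion exchanger of red cells (-4.22). None of these 10 genes overlapped between the arrays of E16 and E20. All of the 5 that rose were dim at E16, so their size depends on the background.

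Among absorptive genes, 17 of 20 measured brush border genes rose and none fell (median log2 change 4.11, camera adjusted p = 3.01e-12), led by the metalloprotease Mep1a (6.60, SE 0.13) and the amino acid transporter subunit Slc7a9 (5.98). The glucose transporter Slc5a1, named in advance, was not called, with a change of 0.91 (SE 0.081); with quantile normalization it was 1.00 and passed. Of 19 genes of lipid absorption and lipoprotein assembly, 16 rose (median 4.32, camera adjusted p = 7.52e-13), among them Apoa4 (7.19, SE 0.076) and the fatty acid binding protein Fabp2 (6.88, SE 0.15). The fatty acid translocase Cd36 alone fell (-1.01), and lost its call when arrays were centred (-0.96) or weighted (-0.95), and in a test against a 2-fold change. In intestine E16 replicate 9, which carried more liver and pancreas transcripts than its group, Apoa1 stood at 9.45, against 6.70 in the next array. Bile acid and ileal transport genes rose in 5 of 11 cases (median 0.97, camera adjusted p = 5.50e-04; adjusted p = 0.167 with an estimated correlation), led by the export pump Abcc2 (4.06) and the bile acid transporter subunit Slc51a (3.56). Fatty acid oxidation and ketogenesis genes rose in 12 of 22 cases (median 1.14, camera adjusted p = 3.09e-09), including Ehhadh (2.24) and Acadm (2.18). Of 33 oxidative phosphorylation genes 2 rose, Sdha (1.24) and Uqcrc1 (1.07, or 0.97 and not called with quantile normalization), and the list as a whole lay higher (median 0.47, camera adjusted p = 3.97e-06; adjusted p = 0.240 with an estimated correlation).

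Secretory and epithelial lists moved the same way. Of 12 goblet cell genes 10 rose (median 3.91, camera adjusted p = 2.01e-09), with Muc13 at 5.57 and the mucin Muc2 at 4.21 (SE 0.077). Of 16 enteroendocrine genes 8 rose (median 1.03, camera adjusted p = 5.31e-06), with the hormones Sct at 4.84 and Gcg at 4.29. Tight junction and adhesion genes rose in 18 of 23 cases (median 2.83, camera adjusted p = 1.99e-12), with Cdh17 at 5.71 and Cldn2 at 5.24. Of 21 endodermal and epithelial transcription factors 10 rose (median 0.93, camera adjusted p = 3.97e-06), led by the intestinal regulators Cdx2 (4.31) and Hnf4a (4.17), and Foxp2 fell (-2.57). The crypt stem cell marker Lgr5 rose by 1.80 (SE 0.085), while 1 of 10 measured stem and progenitor genes rose, 1 fell and the list was not called (camera adjusted p = 0.540), with a median of -0.0020 and a mean of 0.091.

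Antigen presentation genes rose in 12 of 17 cases (median 1.85, camera adjusted p = 1.71e-07), with the immunoproteasome subunits Psmb8 at 4.80 and Psmb9 at 4.24. Myeloid genes rose in 5 of 18 cases (median 0.39, camera adjusted p = 0.00943; adjusted p = 0.434 with an estimated correlation), including the scavenger receptor Cd163 (1.47) and the complement component C1qa (1.37). Glucocorticoid-responsive genes rose in 8 of 24 cases (median 0.49, camera adjusted p = 0.00514; adjusted p = 0.272 with an estimated correlation). These were led by the gluconeogenic enzyme Pck1 (5.90) and the metallothionein Mt2A (4.89), and Hsd11b2, which inactivates glucocorticoids, fell (-1.74). Xenobiotic metabolism genes rose in 5 of 30 cases (median 0.19, camera adjusted p = 0.0204; adjusted p = 0.177 with an estimated correlation), with Gsta3 at 5.39 and Cyp3a9 at 4.83, and Aldh1a1 fell (-1.69). Of the lists of lung genes, the surfactant and the ion transport list lay higher in intestine as well. Of 19 surfactant and alveolar type II genes 9 rose, led by the phosphate transporter Slc34a2 (4.30) and the transcription factor Cebpa (3.53). Fabp5 fell (-1.13), and the camera adjusted p was 0.00142 (adjusted p = 0.240 with an estimated correlation). The surfactant proteins themselves did not change by the criteria used, Sftpb standing at 6.16 and 6.26 and Sftpa1 at 5.50 and 5.45 log2 units. Of 18 genes of lung liquid transport 8 rose, with the sodium-proton exchanger Slc9a3 at 4.69 and the bicarbonate transporter Slc4a4 at 2.61 (camera adjusted p = 0.00231; adjusted p = 0.138 with an estimated correlation), and Hsd11b2, which is in this list too, fell. Alveolar type I genes (median -0.16, camera adjusted p = 0.727), club cell genes (0.031, adjusted p = 0.863) and ciliated cell genes (-0.058, adjusted p = 0.788) were not called as lists in intestine.

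Of the lists that lay lower at E20 in the intestine, the Hox list held with an estimated correlation. Of its 20 measured members 13 fell (median -1.58, camera adjusted p = 4.69e-08), with Hoxd10 at -4.04 and Hoxa10 at -4.00. Erythroid genes fell in 14 of 19 cases (median -2.92, camera adjusted p = 3.52e-07; adjusted p = 0.219 with an estimated correlation). Enteric neuron and glia genes fell in 10 of 22 cases (median -0.88, camera adjusted p = 0.0226; adjusted p = 0.379 with an estimated correlation), with the neuronal Stmn2 at -2.04 and the transcription factor Hand2 at -2.01, whereas the neuropeptide Vip rose (1.75). Elastic fibre genes fell in 7 of 17 cases (median -0.82, camera adjusted p = 0.00786; adjusted p = 0.483 with an estimated correlation), with Ltbp1 at -2.17 and Mfap2 at -1.5. The DNA replication list lay lower (median -0.55, camera adjusted p = 2.50e-06; adjusted p = 0.352 with an estimated correlation), although Gins1 (-1.11) was its only called gene among 32. In a test against a 2-fold change Gins1 lost its call (adjusted p = 0.403), as did Fabp5 (0.422) and Uqcrc1 (1). The proliferation marker Mki67 (0.29, SE 0.072) and the growth factor Igf2 (0.45, SE 0.11) were not called.

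In all, 1250 genes were higher and 890 lower at E20 in the intestine by the limma fit, and 559 of the rises and 120 of the falls reached 4-fold. Of the 46 lists 15 lay higher and 5 lower, and 9 of these calls held with an estimated correlation. The camera adjusted p was then 0.0112 for brush border and lipid absorption, and 0.0171 for goblet cell and tight junction genes. It was 0.0229 for fatty acid oxidation, endodermal transcription factors and Hox genes, 0.0331 for antigen presentation and 0.0351 for enteroendocrine genes. Without a fold minimum 4195 genes were higher and 5964 lower, so that falls outnumbered rises among small changes. The median change of all genes was -0.086, and -0.037 when arrays were centred. A shift in the level of the arrays and many small falls were therefore not told apart. Pancreas transcripts lay 1.05, 1.20 and 1.09 log2 units above their group median in intestine E16 replicates 6, 8 and 9, and liver transcripts 1.35 above it in replicate 9 and 0.80 above it in intestine E20 replicate 9.

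**Figure D2:**
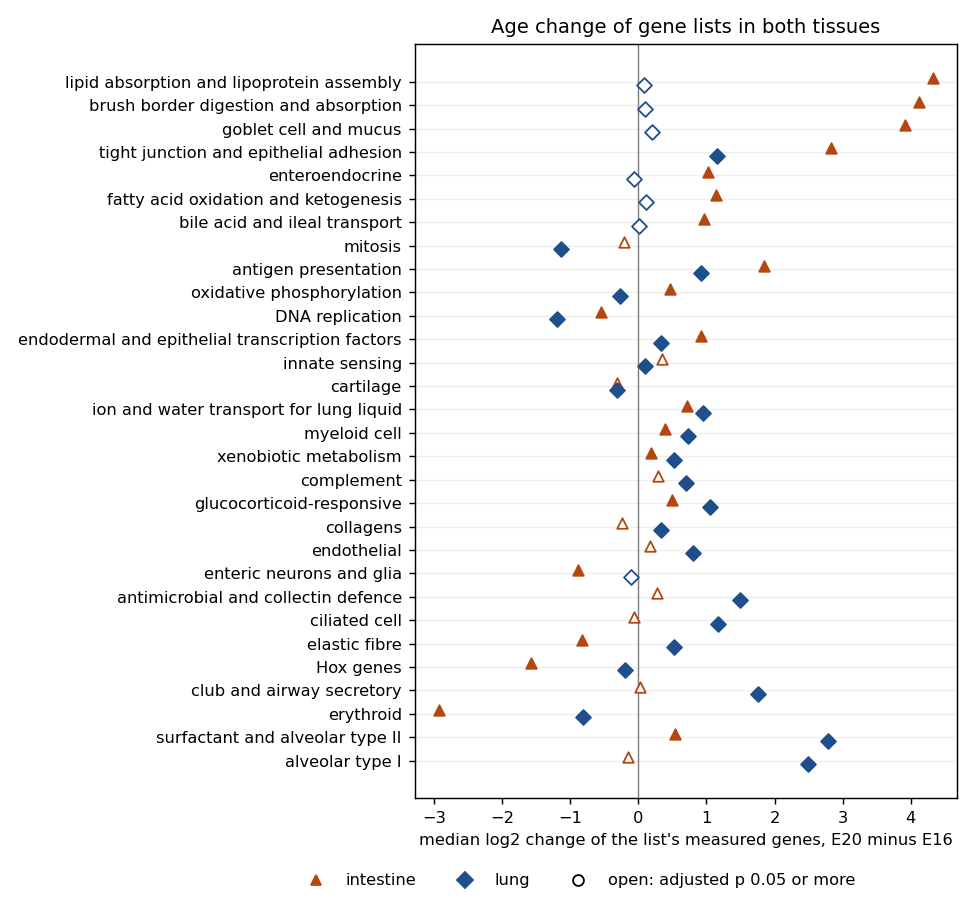
Median log2 change (E20 minus E16, x axis) of the measured members of the 30 gene lists called in either tissue (y axis), with triangles for intestine and diamonds for lung; open symbols mark an adjusted p of 0.05 or more in camera with the preset correlation. The medians of absorptive lists reach 4.32 in intestine against 0.09 in lung, and that of the surfactant list 2.78 in lung against 0.54 in intestine.

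In the lung, surfactant, alveolar, airway secretory and ciliated cell transcripts were higher at E20. Most genes of DNA replication and mitosis were lower, with both list calls lost at an estimated correlation (adjusted p = 0.0920 and 0.126). The largest rise was that of the surfactant protein gene Sftpb, from 6.35 ± 0.12 to 13.49 ± 0.32 log2 units (SD, n = 10 arrays each; change 7.13, SE 0.11, limma adjusted p = 2.13e-38). Next came Sftpa1 (6.97), the phosphate transporter Slc34a2 of alveolar type II cells (6.50), the chitinase Chia (6.0) and Sftpd (5.81). The largest falls were in Hbz (-5.51, SE 0.13, limma adjusted p = 9.03e-32) and in the cartilage gene Cnmd (-4.35). Crabp2, which binds retinoic acid (-4.33), the cartilage collagen Col9a1 (-4.19) and Hbe1 (-3.75) followed. The arrays of E16 and E20 did not overlap for any of these 10 genes. Sftpb, Sftpa1 and Chia were dim at E16.

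Of 19 surfactant and alveolar type II genes 12 rose and none fell (median 2.78, camera adjusted p = 1.48e-11). Sftpc, the surfactant protein gene already high at E16 (11.18 ± 0.37, SD, n = 10), reached 14.83 ± 0.03 (change 3.65, SE 0.11), close to the top of the scale, and the lipid transporter Abca3 rose by 3.84 (SE 0.15). Alveolar type I genes rose in 14 of 16 cases (median 2.48, camera adjusted p = 2.48e-11), led by the receptor Ager (5.04) and the chloride channel protein Clic5 (5.00). The water channel Aqp5 was not called (0.60, SE 0.087). In lung E20 replicates 1, 6 and 8, which held more liver or mesothelium transcripts, the alveolar type I list stood at 11.29, 11.32 and 11.22, against 11.51 to 11.97 in the other arrays. Club and airway secretory genes rose in 8 of 10 cases (median 1.76, camera adjusted p = 1.45e-06), with the secretoglobins Scgb1a1 at 5.24 (SE 0.11) and Scgb3a1 at 5.01 (SE 0.30). Of 12 ciliated cell genes 7 rose (median 1.17, camera adjusted p = 2.04e-06), with the axonemal genes Dynlrb2 at 3.70 and Rsph1 at 3.02, and the ciliogenesis regulator Foxj1 rose by 1.26 (SE 0.075). Ion and water transport genes rose in 8 of 18 cases (median 0.95, camera adjusted p = 6.69e-05), led by the sodium channel subunit Scnn1a (4.36, SE 0.19) and its activating protease Prss8 (2.48).

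**Figure D3:**
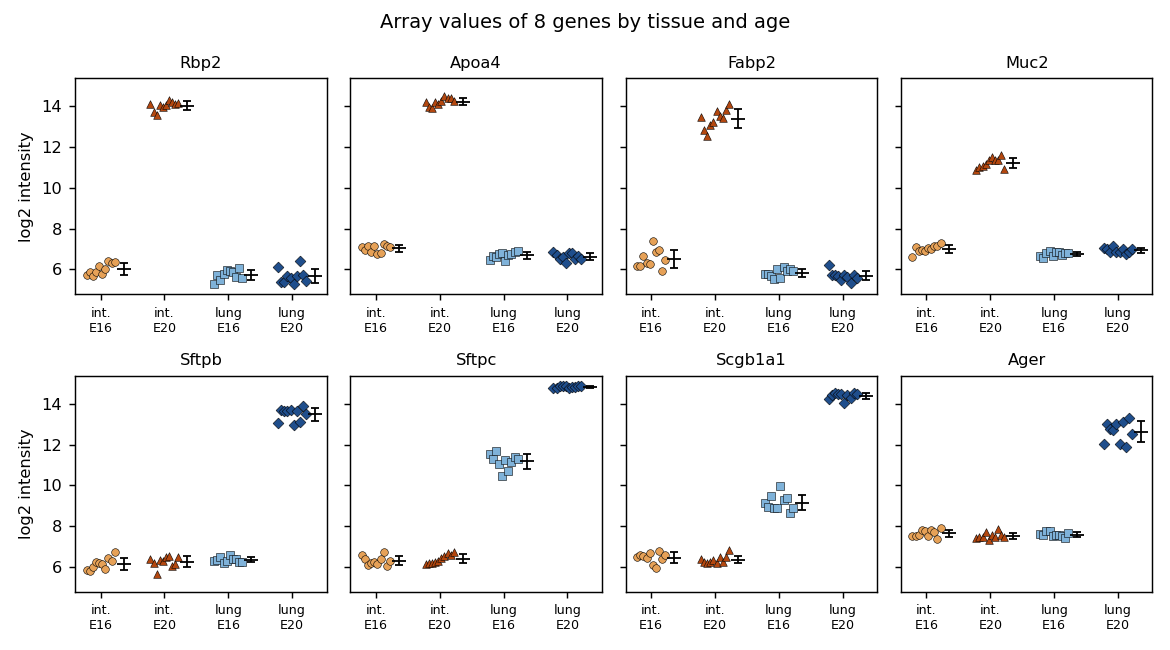
Log2 intensity (y axis) of 8 genes in each array of the 4 groups (x axis), with points spread sideways for display and bars for the mean and SD of 10 arrays. Rbp2, Apoa4, Fabp2 and Muc2 stand apart in intestine at E20, Sftpb and Ager in lung at E20, and Sftpc and Scgb1a1 are already higher in lung than in intestine at E16.

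Complement genes rose in 5 of 14 cases in the lung (median 0.71, camera adjusted p = 6.95e-05), with C3 at 3.53 and Cd55 at 2.96. Xenobiotic metabolism genes rose in 12 of 30 (median 0.53, camera adjusted p = 6.69e-05), with Sult1a1 at 5.43 and Ces1d at 5.29. The exporter Abcg2 fell (-1.20), a call lost in a test against a 2-fold change (adjusted p = 0.418). Antimicrobial and collectin genes rose in 10 of 18 cases, Reg3a fell (-1.83), and the list lay higher (median 1.5, camera adjusted p = 4.97e-05; adjusted p = 0.0920 with an estimated correlation). Its largest changes were those of the collectins Sftpa1 and Sftpd. Antigen presentation genes rose in 8 of 17 cases (median 0.92, camera adjusted p = 3.70e-05; adjusted p = 0.0920 with an estimated correlation), with Cd74 at 2.72 and the class II gene RT1-Bb at 2.28. Myeloid genes rose in 7 of 18 cases (median 0.73, camera adjusted p = 2.22e-04; adjusted p = 0.265 with an estimated correlation), with Cd163 at 2.86 and Lcp1 at 1.92. Innate sensing genes rose in 4 of 16 cases, including Lbp (1.45) and Nod1 (1.38), and the list was called narrowly (camera adjusted p = 0.0483; adjusted p = 0.104 with an estimated correlation). That call was lost with quantile normalization (adjusted p = 0.0537), in bright genes only (0.0635), with averaged probe sets (0.0525) and without the arrays that hold other tissues (0.0534).

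Glucocorticoid-responsive genes rose in 12 of 24 cases in lung (median 1.06, camera adjusted p = 8.76e-06; adjusted p = 0.0781 with an estimated correlation), with Sult1a1 first and the transcription factor Klf15 at 3.71. Tight junction and adhesion genes rose in 12 of 23 (median 1.16, camera adjusted p = 9.91e-07; adjusted p = 0.0920 with an estimated correlation), with Cldn18 at 3.79 and Krt19 at 2.55. Endodermal and epithelial transcription factors rose in 5 of 21 (median 0.33, camera adjusted p = 0.0214; adjusted p = 0.270 with an estimated correlation), with Klf5 at 2.89 and Cebpa at 2.78. In the vessel wall and matrix, endothelial genes rose in 6 of 20 cases (median 0.81, camera adjusted p = 3.70e-05; adjusted p = 0.265 with an estimated correlation), with Emcn at 1.64 and Cldn5 at 1.37. Elastic fibre genes rose in 7 of 17 (median 0.52, camera adjusted p = 0.0171; adjusted p = 0.555 with an estimated correlation), led by elastin, Eln (2.74, SE 0.14), and Mfap5 (2.48). Collagens rose in 6 of 19 (median 0.33, camera adjusted p = 0.0155; adjusted p = 0.555 with an estimated correlation), with Col6a3 at 2.37 and Col6a2 at 1.53, the latter at 0.81 and not called when its probe sets were averaged.

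Of 32 DNA replication genes 27 fell in the lung (median -1.19, camera adjusted p = 3.53e-15; adjusted p = 0.0920 with an estimated correlation), including the origin recognition subunit Orc1 (-2.45) and Mcm10 (-1.95). Of 27 mitosis genes 16 fell (median -1.13, camera adjusted p = 3.74e-14; adjusted p = 0.126 with an estimated correlation), with the checkpoint kinases Ttk at -1.72 and Bub1b at -1.65. In lung E20 replicates 1, 6 and 8 the mitosis list stood at 10.40, 10.34 and 10.48, against 9.74 to 10.17 in the other arrays. Mki67 stood just short of the fold threshold (-0.94, SE 0.072) and passed it when arrays were centred (-1.02) or without the arrays that hold other tissues (-1.04), and Igf2 was not called (-0.66, SE 0.11). Erythroid genes fell in 7 of 19 cases (median -0.81, camera adjusted p = 0.0109; adjusted p = 0.555 with an estimated correlation) and cartilage genes in 5 of 16 (median -0.32, camera adjusted p = 0.00472; adjusted p = 0.0997 with an estimated correlation). Hox genes fell in 5 of 20 cases, Hoxb6 (-2.65) and Hoxb7 (-1.32) among them (median -0.19, camera adjusted p = 0.0381; adjusted p = 0.463 with an estimated correlation). The Hox call was lost with quantile normalization (adjusted p = 0.0530), in bright genes only (0.0635) and without the arrays that hold other tissues (0.0534). The oxidative phosphorylation list lay lower with none of its 33 genes called (median -0.27, camera adjusted p = 0.00124; adjusted p = 0.463 with an estimated correlation).

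By the limma fit, 1016 genes were higher and 658 lower at E20 in the lung, of which 293 and 56 changed at least 4-fold. Rises made up 60.7% of the calls, but 52.4% when arrays were centred. Centring moved the median change of all genes in lung from -0.0064 to -0.086, so the excess of rises depends on the level of the arrays. Of the 46 lists 17 lay higher and 6 lower, and 7 of these calls held with an estimated correlation. The camera adjusted p was then 0.0127 for surfactant and alveolar type I genes and 0.0167 for club cell genes. It was 0.0101 for ciliated cell and 0.0452 for ion transport genes. Complement and xenobiotic metabolism lists held as well. Some lung samples also stood above their group for transcripts of other tissues. Liver transcripts lay 1.71 and 1.74 log2 units above their group median in lung E20 replicates 1 and 8, muscle transcripts 1.44 and 1.41 above it in lung E16 replicates 5 and 9, and mesothelium transcripts 0.84 above it in lung E20 replicate 6. Albumin transcript (Alb) had a median of 10.50 in lung at E16 and 6.35 at E20. At E16 it ranged from 8.20 to 11.23 in lung, and Afp from 8.76 to 11.56, although the liver list was not called for age in lung. Arrays were picked by their distance from their own group median, so leaving them out does not remove a signal of a whole group.

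**Figure D4:**
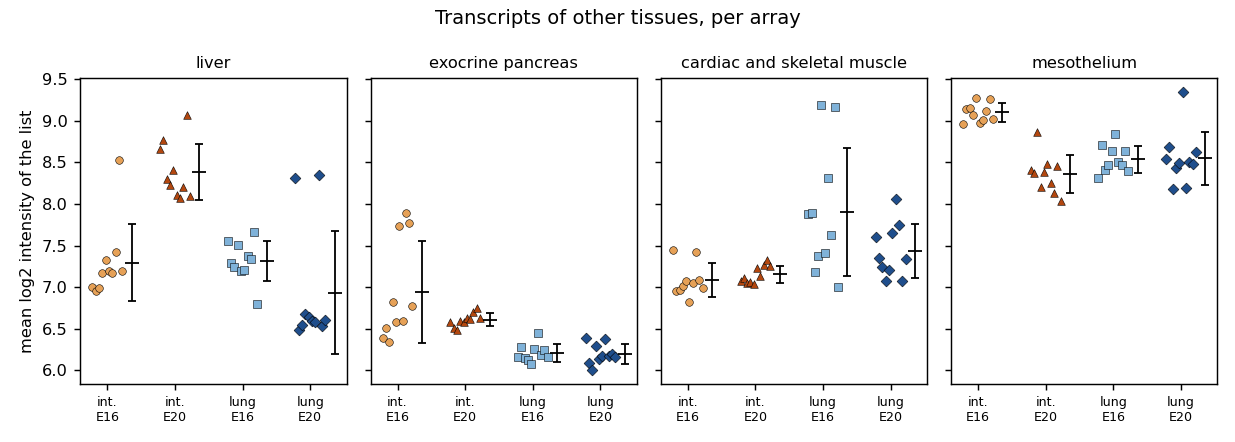
Mean log2 intensity (y axis) of the measured members of 4 lists of other tissues in each array of the 4 groups (x axis), with points spread sideways for display and bars for the mean and SD of 10 arrays. Liver transcripts reach 8.31 and 8.35 in a pair of lung E20 arrays whose group median is 6.60, and muscle transcripts 9.20 and 9.16 in a pair of lung E16 arrays.

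The test of the difference between the age changes asked which genes changed differently in both organs. The largest differences towards lung were those of the surfactant protein genes Sftpb (7.04, SE 0.16, limma adjusted p = 1.40e-32) and Sftpa1 (7.01). Dlk1, an imprinted gene of the Notch ligand family (6.39, SE 0.34), the surfactant protein gene Sftpd (6.14) and the chitinase Chia (6.07) followed. The largest differences towards intestine were those of Apoa1 (-8.88, SE 0.48, limma adjusted p = 1.18e-19), Rbp2 (-8.07), Mttp (-7.91), Apoc2 (-7.91) and Prap1 (-7.55), of which Apoa1, Mttp and Apoc2 are in the lipid absorption list. Apoa1 fell in lung (-1.36), where replicate 10 of E16 was the lowest of its group for Apoa1 (6.18) and for the liver list (6.79). In 66 genes the changes were called in opposite directions. Egfl6 fell by 3.04 in intestine and rose by 2.18 in lung, and Dlk1 fell by 2.00 and rose by 4.38. Emp2, a membrane protein of alveolar type I cells, fell by 1.84 and rose by 4.15. Phactr1 fell by 2.40 and rose by 1.79, and Aldh1a1, a retinaldehyde dehydrogenase, fell by 1.69 and rose by 1.74.

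Counted over all genes, 1298 had a more positive change in lung and 1205 a more positive change in intestine. The share towards lung was 51.9%, and fell under an even split when arrays were centred (42.4%) or quantile normalized (49.3%). Of the lists, 11 differed towards lung and 12 towards intestine, and 5 held with an estimated correlation. These were lipid absorption (median difference -3.28, camera adjusted p = 4.30e-12), brush border (-3.77, camera adjusted p = 3.03e-09), alveolar type I (2.52, camera adjusted p = 3.40e-09), club cell (2.13, camera adjusted p = 6.66e-06) and ciliated cell (1.62, camera adjusted p = 5.88e-05). The elastic fibre list, lower in intestine and higher in lung, differed by a median of 1.54 (camera adjusted p = 2.51e-06; adjusted p = 0.202 with an estimated correlation). Mitosis genes differed by -0.92 (camera adjusted p = 4.95e-09; adjusted p = 0.291 with an estimated correlation), with a median of -0.21 in intestine (none of 27 called, camera adjusted p = 0.158) against -1.13 in lung. Centring each array moved the median difference of all genes from 0.032 to -0.098.

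Comparing the tissues at each age, lung was set apart by the limb and lung transcription factors Tbx5 and Tbx4, by Sftpc, by Lamp3, a membrane protein of lamellar bodies, and by Phex, an endopeptidase. Tbx5 was higher in lung by 7.15 at E16 and 6.36 at E20 (SE 0.20 each), Sftpc by 4.87 and 8.42, Lamp3 by 4.55 and 8.54, Tbx4 by 6.19 and 6.53 and Phex by 5.85 and 6.01. Intestine was set apart by Cps1, a urea cycle enzyme (-3.78 at E16 and -8.14 at E20, lung minus intestine, SE 0.31 each), by the lectin Lgals4 (-3.34 and -8.16), by the Bmp antagonist Grem1 (-5.41 and -5.97), by Gpr15lg (-3.32 and -6.34) and by Pcp4 (-4.39 and -4.94). For these 10 genes the arrays of the tissues did not overlap at either age. All 5 lung genes were dim in intestine at both ages, as were Cps1, Lgals4, Grem1 and Gpr15lg in lung, and Pcp4 in lung at E20. Their sizes therefore depend on the background, and Sftpc in lung at E20 lay close to the top of the scale.

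At E16, 303 genes were higher in lung and 427 higher in intestine, and at E20 the numbers were 1125 and 1167 by the same limma fit. At E16, 5 lists lay higher in lung and 6 higher in intestine. Of these, enteric neurons and glia held with an estimated correlation (13 of 22 genes higher in intestine, median -1.34, camera adjusted p = 2.72e-12). Endothelial genes were higher in lung in 11 of 20 cases (median 1.13, camera adjusted p = 3.39e-11; adjusted p = 0.136 with an estimated correlation), and smooth muscle genes higher in intestine in 9 of 17 (median -1.35, camera adjusted p = 2.64e-08; adjusted p = 0.310 with an estimated correlation). The mitosis list lay higher in lung at E16 (median 0.42, camera adjusted p = 5.66e-10) and lower at E20 (-0.52, camera adjusted p = 5.01e-04), with none of its 27 genes called at either age (adjusted p = 0.444 and 0.521 with an estimated correlation). The DNA replication (0.17), distal lung bud (0.17) and surfactant (0.16) lists also lay higher in lung at E16, the last of these not in bright genes only (adjusted p = 0.0964). With an estimated correlation these calls were lost (camera adjusted p = 0.672, 0.136 and 0.672). Hox genes (-0.80), enteroendocrine genes (-0.45) and interstitial cells of Cajal (-0.52) lay higher in intestine. Those calls were lost as well with an estimated correlation (camera adjusted p = 0.136, 0.310 and 0.310). The exocrine pancreas list also lay higher in intestine (-0.44, camera adjusted p = 0.0379), and intestine E16 replicates 6, 8 and 9 stood 1.05 to 1.20 above their group median for it. Its call was lost with an estimated correlation (camera adjusted p = 0.688), without the arrays that hold other tissues (0.125), with quantile normalization (0.111) and with array weights (0.0579). At E20, 12 lists lay higher in lung and 13 higher in intestine, and alveolar type I, ciliated cell, lipid absorption, brush border and enteroendocrine lists held with an estimated correlation. The call of the myeloid list there, higher in lung, was lost in bright genes only (adjusted p = 0.0518). The amount of RNA labelled differed between tissues at both ages, and centring each array moved the median lung minus intestine difference at E16 from -0.11 to 0.044 and the share of calls that were higher in lung from 41.5% to 52.9%.

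Many genes changed in the same direction in both organs. Those that rose in both with the largest smaller change were Clic5 (5.26 in intestine and 5.00 in lung, SE 0.17 each), Slc34a2 (4.30 and 6.50), the acute-phase gene Saa3 (4.05 and 4.72), the integrin subunit Itgb6 (4.05 and 3.88) and the lactonase Pon3 (3.86 and 4.13). Those that fell in both were Hbz (-7.41 and -5.51), Hbe1 (-6.29 and -3.75), Hbg1 (-5.49 and -3.46), Crabp2 (-2.96 and -4.33) and the cartilage collagen Col2a1 (-2.57 and -3.74). In total 362 genes rose in both tissues, against 89.3 expected of independent lists (two-sided Fisher's exact test across genes, p = 1.14e-139), and 179 fell in both, against 41.2 (p = 3.82e-69). Rises in intestine with falls in lung numbered 12, against 57.9 expected (p = 4.20e-14), and falls in intestine with rises in lung 54, against 63.6 (p = 0.226). Across the 14217 genes, which are not independent replicates, the age changes of both tissues correlated at r = 0.338 (Spearman's rho 0.349). Of 1533 genes called in intestine alone 1072 were also called in the test of the difference, as were 626 of 1067 called in lung alone. For the others a difference that passed both the adjusted p and the 2-fold minimum was not shown. Smaller differences between the tissues remain possible for them.

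**Figure D5:**
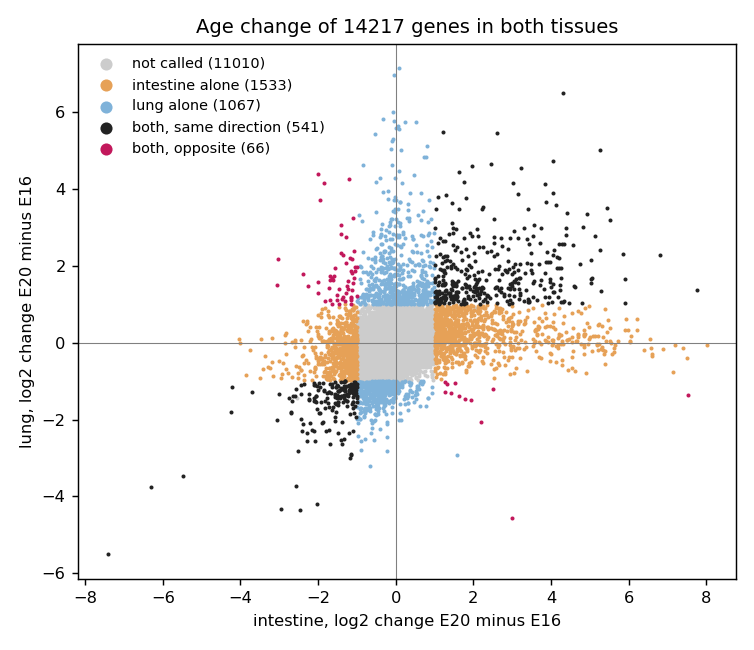
Log2 change from E16 to E20 in intestine (x axis) and lung (y axis) for 14217 genes, with a point per gene coloured by its calls. The plot shows 541 genes called in the same direction in both tissues, 66 in opposite directions, 1533 called in intestine alone, 1067 in lung alone and 11010 in neither.

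The remaining lists passed camera's threshold in neither age comparison. Smooth muscle genes had a median change of 0.21 in intestine (camera adjusted p = 0.227) and 0.25 in lung (camera adjusted p = 0.0573), and distal lung bud genes of -0.44 and -0.29 (camera adjusted p = 0.129 and 0.559). Imprinted and fetal growth genes had medians of -0.38 and -0.17 (camera adjusted p = 0.198 and 0.206), although 8 of 22 fell and 1 rose in intestine. Medians in intestine and lung were -0.13 and 0.030 for the insulin-like growth factor axis (camera adjusted p = 0.641 and 0.660), -0.18 and -0.13 for Wnt, Bmp and Notch signalling (0.267 and 0.909). They were 0.29 and 0.033 for glycolysis (0.385 and 0.798), 0.15 and 0.33 for antioxidant defence (0.174 and 0.121), 0.060 and 0.17 for lymphocytes (0.540 and 0.567) and -0.16 and 0.23 for interstitial cells of Cajal (0.267 and 0.301). Of the other tissues, the medians were 0.23 and -0.17 for liver (camera adjusted p = 0.102 and 0.909), -0.22 and -0.056 for exocrine pancreas (0.727 and 0.951). They were 0.0056 and 0.075 for stomach and oesophagus (0.736 and 0.801), 0.079 and -0.36 for cardiac and skeletal muscle (0.727 and 0.334), -0.41 and -0.11 for mesothelium (0.353 and 0.801) and -0.0051 and 0.14 for thyroid and other neck endocrine tissue (0.727 and 0.568). The liver list passed in intestine when probe sets were averaged (adjusted p = 0.0344) and without the arrays that hold other tissues (0.0142), and the cartilage list did so as well (0.0389 and 0.0361, against 0.0644 with all arrays). Innate sensing genes, not called in intestine (camera adjusted p = 0.0644), passed there in bright genes only (0.00811), with averaged probe sets (0.0370) and without the arrays that hold other tissues (0.0454). The sex-linked list had 4 measured members and was not tested.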

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

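The tests that weigh an explanation for blood, liver and Hox transcripts were chosen after the result was seen, the second liver list before the values of its own genes were, whereas the other splits of the samples were planned before the data were examined. Among 502 groups of 10 values examined, 39 held an array whose gap to its nearest neighbour was large for the range of its group, against 25.1 that chance gives, since chance flags about 1 in 20 groups. Of these 18 were list means and 21 single genes. Intestine E16 replicate 8 accounted for 9, lung E16 replicate 7 for 6 and lung E20 replicate 6 for 4, and lung E16 replicate 6 and intestine E16 replicate 9 for 3 each. The lowest intensity of intestine E16 replicate 8 was 37.1, against 16.8 in the next array of its group. Its lower quartile was 118, against 110 in the next. Its flags were all at the high end, so raised low intensities and a change in these lists and genes were not told apart.

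In the following, the number after each name is the gap divided by the range of the 10 arrays. Intestine E16 replicate 8 was the highest of its group for the brush border list (0.649), the surfactant list (0.659), the ciliated cell list (0.475), the ion and water transport list (0.507), Slc7a9 (0.468), Slc9a3 (0.528), Cd163 (0.515), Cyp3a9 (0.568) and Itgb6 (0.513). Intestine E16 replicate 9 was the highest for the liver list (0.703), Apoa1 (0.745) and Apoc2 (0.582), and replicate 1 for Hoxa10 (0.497). In intestine at E20, replicate 9 was the highest for the club cell list (0.735), replicate 2 for the erythroid list (0.484), replicate 3 for the mesothelium list (0.475) and replicate 1 for Gsta3 (0.589), and the lowest were replicate 3 for Sftpb (0.482) and replicate 8 for Col2a1 (0.570).

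Lung E16 replicate 7 was the highest of its group for the brush border list (0.484), the bile acid list (0.534), the Hox list (0.626), the exocrine pancreas list (0.472), Cd163 (0.473) and Lgals4 (0.479). Lung E16 replicate 6 was the highest for the antigen presentation list (0.50) and Cd74 (0.493) and the lowest for Mki67 (0.557). Replicate 9 was the highest for the fatty acid oxidation list (0.501), and the lowest were replicate 2 for the endothelial list (0.512), replicate 10 for the liver list (0.467) and Apoa1 (0.521), and replicate 1 for Foxj1 (0.570). In lung at E20, replicate 6 was the highest for the mesothelium list (0.567) and the lowest for the distal lung bud list (0.534), Rsph1 (0.530) and Abca3 (0.484), while replicate 2 was the lowest for Dynlrb2 (0.661) and replicate 1 for Nod1 (0.578).

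A difference between the tissues in the age change, tested as lung change minus intestine change, singled out 23 lists by camera and 23 of the 28 genes whose changes in both tissues are given. Median differences were positive for the lists of alveolar type I (2.52), club cell (2.13), surfactant (1.92), erythroid (1.68), ciliated cell (1.62), elastic fibre (1.54), antimicrobial (0.96), collagen (0.66), Hox (0.59), interstitial cell of Cajal (0.50) and endothelial (0.42) genes. They were negative for brush border (-3.77), lipid absorption (-3.28), goblet cell (-2.81), enteroendocrine (-1.07), tight junction (-1.07), fatty acid oxidation (-1.02), mitosis (-0.92), oxidative phosphorylation (-0.68), bile acid (-0.65), DNA replication (-0.59), antigen presentation (-0.46) and endodermal transcription factor (-0.21) genes. Of these, 5 lists held with an estimated correlation (lipid absorption, brush border, alveolar type I, club and ciliated cell). The call for interstitial cells of Cajal was also lost with quantile normalization (adjusted p = 0.0525), in bright genes only (0.0532) and with averaged probe sets (0.0748). That for endodermal transcription factors was lost in bright genes only (0.0823) and with array weights (0.0551). Not called with all genes and arrays, the complement (0.0373) and mesothelium (0.0260) lists passed in bright genes only, and the liver list passed without the arrays that hold other tissues (0.0126).

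Single genes with a positive difference were Sftpb (7.04), Sftpa1 (7.01), Dlk1 (6.39), Sftpd (6.14), Chia (6.07), Emp2 (5.99), Egfl6 (5.22), Phactr1 (4.19), Aldh1a1 (3.43), Hbe1 (2.54), Slc34a2 (2.20), Hbg1 (2.03), Hbz (1.89) and Cd163 (1.39). Those with a negative difference were Apoa1 (-8.88), Rbp2 (-8.07), Mttp (-7.91), Apoc2 (-7.91), Prap1 (-7.55), Crabp2 (-1.38), Mki67 (-1.24), Col2a1 (-1.16) and Igf2 (-1.12).

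Other splits of the same arrays were made, 100 for each comparison with the real one included. None of the others called as many genes as the real groups (1 of 100 each, the real one). That is the smallest share that 100 splits can give. For the age and tissue comparisons it argues against a chance division of the arrays and against nothing else. The groups already lay apart on the first pair of principal components, so this outcome was hardly in doubt. The splits for the difference and for shared calls also removed the age effect within each tissue. They therefore cannot tell whether changes differ between tissues or are shared. The real and the highest other counts were 2140 and 889 for age in intestine, 1674 and 194 for age in lung, 2503 and 1466 for the difference, 730 and 310 for tissue at E16, 2292 and 1701 for tissue at E20, and 541 and 99 for calls shared by both tissues.

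Embryonic globins fell in both tissues, and less blood in the E20 samples is a candidate explanation. Here and below, the interval of a median is taken over the genes of a set and not over arrays. Genes of a list are correlated (estimated at 0.484 for the erythroid list), so these intervals are probably too narrow. In lung, the other 16 erythroid genes had a median change of -0.66 (95% interval -1.14 to 0.10), far from the -3.46 of the embryonic globin that changed least, which argues against less blood as the whole cause. In intestine their median was -2.69 (interval -3.16 to -0.72) against -5.49, so there less blood and a change of globin type cannot be told apart, because the interval spans the point that would decide. Age, which the design names, stays open and was not tested separately from the amount of blood.

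Liver transcripts were high in lung E20 replicates 1 and 8, where Alb stood at 12.10 and 12.29 against at most 6.94 in the others, and Afp at 11.28 and 11.47 against at most 5.94, with Ahsg, Fga, Fgg, Apoh and Serpina1 also highest in both, and Fgb not (6.65 and 6.86, and between 6.47 and 7.39 in all 40 arrays). Because the arrays were picked by the liver list, RNA from liver was tested on a second list of liver genes. Both arrays were the highest pair for 7 of its 18 genes, more than the 0.40 that chance gives but fewer than the 9 set beforehand, so RNA from liver stays open. An array-wide shift is argued against by 87 genes of other tissues, which lay 0.096 above their group median in these arrays (interval 0.032 to 0.134), while the median liver gene lay 1.22 above its own. No biological explanation was tested for single arrays. Lung E20 replicates 1, 6 and 8 stood at -41.4, -46.2 and -42.9 on the second principal component, against -52.7 to -60.9 in the others. They thus lay on the side of lung E16 (5.61 to 15.1). Sftpb was also lowest in these arrays (13.07, 12.98 and 13.11, against 13.48 to 13.90 in the others). Whether these samples differed in stage was not tested and stays open.

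Hox genes fell in intestine, with a median of -1.58. Less posterior gut in the E20 samples, as the whole cause, is argued against by paralogous groups 1 to 5, whose 9 genes had a median of -1.51 (interval -1.89 to -0.80), with 6 called lower; the median was -1.12 in groups 6 to 8 and -2.37 in groups 9 to 13, so a part of the fall may still come from it. A smaller share of all mesenchyme alike was the other candidate for the whole cause. The 53 collagen, smooth muscle and elastic fibre genes had a median of -0.062 (interval -0.48 to 0.063), far from the Hox median. Their level per cell was not measured and may have changed with age, so these genes cannot exclude a smaller share. Elastic fibre genes alone had a median of -0.82 (interval -1.22 to -0.062) and smooth muscle genes one of 0.21 (0.067 to 0.33), so the loss of a part of the mesenchyme stays open as well. Age stays open as untested.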

How the results depend on the processing

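The Xist covariate, leaving out the arrays that hold other tissues and leaving out intestine E16 replicate 8 were chosen after the data were seen, and the other settings before. All 13 counts of calls stayed within 1.5 times under quantile normalization, centring, bright genes, averaged probe sets, exclusion of cross-hybridising probe sets, fits on the groups compared (which give no separate value for the difference), array weights, a variance trend, the Xist covariate and both exclusions of arrays, and no call turned its direction. Without the 9 arrays that hold other tissues, calls numbered 2162 in intestine, 1902 in lung, 2713 for the difference, 757 at E16 and 2380 at E20.

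With the adjusted p alone, higher and lower calls numbered 4195 and 5964 in intestine, 4692 and 4786 in lung, 5012 and 4399 for the difference, 3388 and 5721 at E16 and 4350 and 6047 at E20, with 2162 higher and 2856 lower in both tissues and 2223 in opposite directions. At a fold of 1.5 they were 2123 and 2264, 1938 and 1809, 2602 and 2373, 722 and 1195, and 2040 and 2372, with 787, 719 and 289 for both tissues. These rise by construction, as smaller changes pass. A test against a 2-fold change, stricter by construction, gave 533 lower in intestine, 341 lower in lung, 747 and 775 for the difference, 159 and 246 at E16, 230 higher and 83 lower in both and 28 opposite.

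Leaving out each array in turn gave 1240 to 1276 higher and 851 to 927 lower in intestine, 993 to 1039 and 624 to 706 in lung, 1270 to 1328 and 1194 to 1228 for the difference, 294 to 312 and 407 to 439 at E16, 1103 to 1141 and 1157 to 1183 at E20, and 354 to 370 higher and 172 to 188 lower in both tissues, with 64 to 70 opposite.

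Replicate numbers were not taken to pair the samples, since not every pair correlated over 0.1. Deviations of same-numbered intestine and lung arrays correlated at -0.047 to 0.701 at E16 and at -0.140 to 0.395 at E20, and those of both ages at -0.221 to 0.184 in intestine and -0.254 to 0.353 in lung. At E16, 7 of 10 pairs were over 0.1, with a median of 0.273 against -0.038 for different numbers, a hint from the data that some numbers are shared; at E20 4 were, with medians of -0.093 and 0.0021. At E16, 6 intestine and 5 lung arrays of 10 correlated best with their own number, and at E20 1 and 2. With the number as a block, calls numbered 2139, 1674, 2506, 730 and 2292 for intestine, lung, the difference, E16 and E20, and with age and number as a random block (consensus correlation 0.107) 2140, 1674, 2506, 730 and 2292; the block changed the call of none of the 160 gene results given.

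Of the list results for the 5 comparisons, 75 lost their call with an estimated correlation, 4 with quantile normalization (3 gained it), 6 in bright genes only (5 gained it), 2 with averaged probe sets (8 gained it), 2 with array weights and 3 without the arrays that hold other tissues (8 gained it); the cause was not tested. Dim signal limits genes under the 30th percentile of intensity, where background compresses differences, so that large changes from a dim group are uncertain in size.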

Other observations

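The tests of shared numbers and of pooled siblings were chosen after the result was seen. The hypothesis was that arrays of intestine and lung with the same number come from the same embryo, which would give them the same sex. At E20, 6 of 10 same-numbered pairs differed in the sex-linked transcript Xist by over 3 log2 units (at least 7.77, and at most 0.461 in the other pairs), which argues against the hypothesis at that age. At E16, 1 of 10 pairs differed by that much (8.0, and at most 2.60 in the others). By the Y-linked Eif2s3y, 2 pairs differed by over 3 at E16 (at least 4.14) and 6 at E20 (at least 7.17).

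The other hypothesis was that each array holds RNA of several unsorted siblings, in which case at most about 50% of the arrays would show 1 sex alone. In 38 of 40 arrays Xist or Eif2s3y lay above the median level while the other was dim, which argues against it. Intestine E16 replicate 6 (Xist 9.65, Eif2s3y 11.68) and lung E16 replicate 1 (12.76 and 7.74) held both. Pools of siblings of 1 sex stay open.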
